A study of Mus musculus with 20 samples.

How the data were processed

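RNA was measured in 20 samples from 5 mouse pancreatic tumors: bulk tumor, Kras-expressing spheres, surviving cells and re-expressing cells of each. Per the labels' protocols, RNA was extracted with Trizol and a column kit, labelled as biotinylated cRNA and hybridized to an Affymetrix mouse array of 45101 probe sets. The deposited values are linear intensities, from 8.93 to 46304, with 0 values equal to 0 and 4.62% under 16; the normalization that the authors applied is not stated in the labels. All columns of per-sample values were used. The labels give doxycycline as the treatment of every sample, including the surviving cells, whose Kras expression field reads No. Groups follow the group names and the Kras expression field.

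From these intensities log2(value + 16) was computed, so folds of dim genes are understated. Of the probe sets 34958 carry 1 gene symbol, 932 carry several and 9211 none; only those with 1 symbol entered the comparisons. Of these, 34754 have a gene ID in the RefSeq table for mouse assembly GRCm38.p6 and 204 do not, and 0 symbols changed on update. For each of 18194 genes the probe set with the highest mean over the 20 arrays was kept, and genes under the 30th percentile of probe set means (5.83) were left out, which left 14503. Kras was not analysed here, since its probe sets are not among those named.

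Surviving cells were compared with spheres, re-expressing cells with surviving cells, and re-expressing cells with spheres in 1 limma fit of the 15 cultured arrays (12 residual degrees of freedom). Spheres were compared with bulk tumor in a fit of 10 arrays (8 residual degrees of freedom). P values were moderated with empirical Bayes, adjusted by Benjamini-Hochberg over the tested genes, and called under 0.05. The 5 arrays per group and the fit both limit the precision. In the same fit on simulated data with 200 changed genes among 14503, 68, 76, 67 and 70 of 100 genes with a 2-fold change and 93, 91, 93 and 97 of 100 with a 4-fold change were called in the 4 comparisons in this order, 0 in the wrong direction, and 2, 1, 2 and 5 unchanged genes were called. On the same data the fit with the tumor as a block called 90, 93, 93 and 74 of 100 genes with a 2-fold change and 10, 11, 12 and 13 unchanged genes, so part of the shortfall in the cultures comes from leaving the pairing out.

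Samples with the same number come from the same tumor per the labels. This was checked by correlating their deviations from the group means: same-numbered samples correlated at 0.396 to 0.767 for surviving cells and spheres, 0.893 to 0.922 for re-expressing and surviving cells, and 0.419 to 0.754 for re-expressing cells and spheres, each best with its own number in 5 of 5. For spheres and bulk tumor the range was 0.0153 to 0.398, with 3 of 5 best with their own number. The fit with the tumor as a block is the paired alternative.

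Gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over 37 lists with at least 5 tested members, of 38. The 26 pathway lists are respiratory complex I, complexes II to IV, ATP synthase, mitochondrial ribosome, mitochondrial biogenesis regulators, TCA cycle, glycolysis, pentose phosphate with hexosamine and nucleotide synthesis, fatty acid oxidation, cholesterol and fatty acid synthesis, autophagy, lysosome, MAPK pathway output, DNA replication, mitosis, cell cycle arrest and quiescence, ribosome biogenesis and MYC targets, unfolded protein response and ATF4 targets, NRF2 and antioxidant genes, hypoxia, p53 targets, interferon response, cytokines and NF-kB targets, epithelial genes, mesenchymal genes, and stem and tumor-initiating cell markers. The 12 cell type lists hold markers of acinar, endocrine and ductal cells, fibroblasts, macrophages and monocytes, lymphocytes, neutrophils and mast cells, endothelium, pericytes and smooth muscle, red blood cells, adipocytes, and nerve and Schwann cells. A list's count adjusted over the list alone corrects for its own members only.

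The genes named were picked by a rule. In each comparison it takes the 10 largest changes up and the 10 largest down among genes that pass with the same sign in all 5 pairs, the 4 members of each list with the smallest p among those that pass (or, where none passes, the 2 tested members with the highest mean), and Kras, Dusp6, Spry4, Etv4, Ccnd1, Myc, Mki67, Ppargc1a, Slc2a1, Hk2, Ldha, Cdh1, Vim, Cd44 and Prom1 throughout. Comparisons, lists, filters, this rule and the alternatives were set before the data were examined. The alternatives were no filter, a filter at the 50th percentile, the block, quantile normalization, centring on the array median, the mean of all probe sets of a gene, empirical Bayes with trend and robust options, all 20 arrays or only the 10 compared in the fit, pseudocounts of 1 and 64, each array or each tumor left out, and an estimated inter-gene correlation. The block with an estimated correlation, the simulated groups for the overlap with the block, the exact permutation tests of list means, and all but 2 of the tests of explanations in the closing section were added after the data had been seen. The overlap between ablation and re-expression was set against simulated groups with no effect, and against splits of the surviving-cell arrays between the 2 comparisons. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used. Means are given with the SD over 5 arrays, and SE is the standard error of the log2 change in the fit.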

Results

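The series followed 5 independent mouse pancreatic tumors through 4 states, with 1 Affymetrix expression array per tumor and state (20 arrays). The tumors carried a doxycycline-inducible mutant Kras transgene and a conditional p53 allele. Bulk tumor is the lesion as it grew in the animal. Kras-expressing spheres are tumor cells grown from it in suspension for 8 days with the oncogene on. Surviving cells are what was left of the sphere cultures after 8 days of Kras ablation, and re-expressing cells are surviving cells with Kras switched on again for 24 hours. Per the labels, arrays with the same tumor number came from the same lesion, which gives each comparison 5 matched pairs. Between spheres and bulk tumor the values bear this out only in part, with 3 of 5 best correlated with their own number. Of the 18194 genes with a probe set, 14503 (79.7%) were bright enough to test. Kras itself was not analysed here, because none of the named probe sets carries its symbol.

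Bulk tissue stood apart from every culture. The first principal component held 44% of the variance and placed the 5 bulk tumors on one side and the 15 cultured arrays on the other. Correlations between bulk and cultured arrays ran from 0.817 to 0.889, against 0.907 or more among the cultured arrays. Within the cultures, arrays of the same tumor deviated together. They also share a culture, so tumor of origin and culture history cannot be told apart here. Surviving cells deviated from their group mean most like the spheres of their own tumor in 5 of 5 tumors, and re-expressing cells most like their own surviving cells in 5 of 5. Array medians lay between 84.6 and 94.0 intensity units, with bulk tumor at 92.8 ± 1.29 and spheres at 87.3 ± 1.91 (SD, 5 arrays each).

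**Figure D1:**
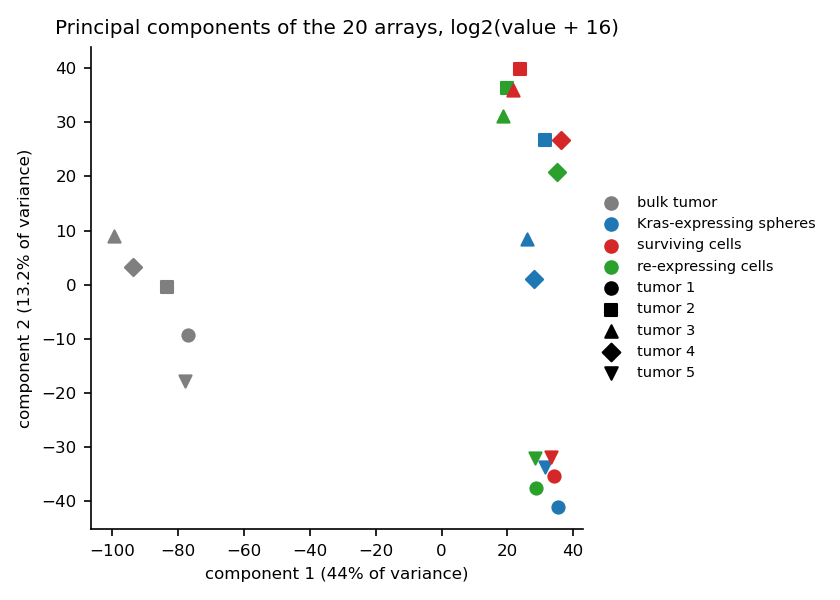
Principal components of the 20 arrays, computed on log2(value + 16), with component 1 (44% of the variance) across and component 2 (13.2%) up. Colors mark the 4 groups and marker shapes the 5 tumors; the 5 bulk tumors lie between -99.7 and -76.9 on component 1 and the 15 cultured arrays between 18.6 and 36.2.

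Surviving cells were first compared with the matched spheres, to see which genes set cells that outlive Kras apart. The comparison cannot separate the response to ablation from selection of the cells that survived it. The transgene is switched by doxycycline, which the labels list for every sample. If the drug was withdrawn for ablation, its own effect is not separated either, here or on re-expression. Transcripts that report MAPK signaling fell in all 5 tumors. Dusp6, which encodes a phosphatase that switches off ERK, fell by 2.52 on the log2 scale (SE 0.20, limma adjusted p = 7.78e-05), 5.73-fold, from 13.22 ± 0.35 in spheres to 10.70 ± 0.40 in surviving cells. The ERK feedback inhibitor Spry4 fell by 2.17 (SE 0.37, adjusted p = 0.00764), the ETS transcription factor Etv4 by 1.80 (SE 0.26, adjusted p = 0.00381), the phosphatase Dusp5 by 2.92 and the immediate-early factor Egr1 by 3.73, each lower in 5 of 5 pairs. Of the 25 tested members of the MAPK output list 8 fell. Adjusted over the list alone 16 fell and 1 rose, and with the tumor as a block 18 fell and 1 rose. As a set the list was lower (median change -0.81, camera adjusted p = 1.55e-14; adjusted p = 0.0289 with an estimated correlation, lost at 0.597 when the block is added to it), and its mean change was -1.29, -1.57, -1.01, -1.85 and -0.64 in tumors 1 to 5. Cyclin D1, Ccnd1, was 0.81 lower in 5 of 5 pairs without passing (adjusted p = 0.0595; 0.00167 with the block), and Myc changed by -0.21 (adjusted p = 0.387).

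Sterol synthesis fell with it. Of 22 genes of cholesterol and fatty acid synthesis 8 fell (13 adjusted over the list alone), and the list mean was lower in 5 of 5 tumors. Msmo1, the methylsterol monooxygenase, fell by 1.28 (SE 0.13, adjusted p = 0.000494), lanosterol synthase Lss by 1.79 (SE 0.26, adjusted p = 0.00381) and the demethylase Cyp51 by 1.44 (SE 0.24, adjusted p = 0.00732). The list median was -0.86 (camera adjusted p = 6.61e-12; adjusted p = 0.538 with an estimated correlation). Genes of ribosome biogenesis and MYC targets also fell as a set, lower in 5 of 5 tumors (median -0.35, adjusted p = 4.06e-08; 0.582 as the adjusted p with an estimated correlation). None of its 40 members passed alone over all genes, 13 fell adjusted over the list alone and 20 fell with the block. The unfolded protein response and ATF4 list fell (median -0.48, lower in 4 of 5 tumors, adjusted p = 0.000382; adjusted p = 0.602 with an estimated correlation), with 2 of 30 members lower, 11 adjusted over the list alone and 12 with the block. Among them Psat1, an enzyme of serine synthesis, fell by 1.61 (SE 0.31, adjusted p = 0.0127).

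The lists of fatty acid oxidation and of the lysosome rose in the surviving cells. Cpt1a, the gate of fatty acid import into mitochondria, rose by 1.18 (SE 0.19, adjusted p = 0.00664), 2.26-fold. The fatty acid oxidation list rose in 5 of 5 tumors (median 0.39, camera adjusted p = 2.32e-05; adjusted p = 0.582 with an estimated correlation), with 2 of 22 members higher, also 2 adjusted over the list alone, and 14 with the block. The lysosome list rose in 5 of 5 tumors too (median 0.20, adjusted p = 0.00344; adjusted p = 0.654 with an estimated correlation), with 2 of 39 members higher, 2 over the list alone and 10 with the block, led by the lysosomal membrane protein Scarb2 at 1.49 (SE 0.20, adjusted p = 0.00259). Respiratory complex I genes were slightly higher (median 0.17, adjusted p = 0.0442; adjusted p = 0.74 with an estimated correlation), 1 of 33 members passing, likewise 1 over the list alone, and 7 with the block. The list mean was above 0 in 5 of 5 tumors, from 0.0234 in tumor 3 to 0.485 in tumor 4. The call was lost without tumor 4 (adjusted p = 0.303) and with a filter at the 50th percentile (0.1). Complexes II to IV (adjusted p = 0.115; 0.049 without tumor 5), ATP synthase (0.338) and the TCA cycle (0.116) did not pass as lists, although Idh2, the mitochondrial isocitrate dehydrogenase, rose by 1.51 (SE 0.30, adjusted p = 0.015). Autophagy did not pass either (adjusted p = 0.115; 0.0273 without tumor 4), while its member Gabarapl1, which acts in autophagosome formation, rose by 1.17 (SE 0.18, adjusted p = 0.00546). Ppargc1a, the coactivator of mitochondrial biogenesis, was 1.49 higher in 5 of 5 pairs and passed only with the block (adjusted p = 0.287, 0.0127 with it).

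Glycolytic genes gave a weaker result. The list of 18 did not pass (median -0.26, adjusted p = 0.0643; 0.0313 with the mean of all probe sets of a gene and 0.049 without tumor 5), with 2 members lower over all genes, 2 lower and 1 higher adjusted over the list alone, and 6 lower and 2 higher with the block. The glucose transporter Slc2a1 fell by 1.43 (SE 0.36, adjusted p = 0.0438) and lactate dehydrogenase Ldha by 0.51 (SE 0.13, adjusted p = 0.0463), both in 5 of 5 pairs. The Slc2a1 call was lost when any 1 array other than the surviving-cell array of tumor 5 was left out (adjusted p up to 0.0982), or with no filter (0.0528), and the Ldha call without any of 8 arrays, all but the sphere array of tumor 1 and the surviving-cell array of tumor 3 (up to 0.112), or with all 20 arrays in the fit (0.0554) or a pseudocount of 1 (0.0511). Neither gene passed with only the 10 arrays compared in the fit (0.055 and 0.126). Hexokinase 2, Hk2, changed by -0.32 (adjusted p = 0.574).

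Interferon-response genes rose as a list (median 0.22, higher in 4 of 5 tumors, adjusted p = 0.0106; adjusted p = 0.74 with an estimated correlation). Of its 31 members 3 rose, 6 rose and 1 fell adjusted over the list alone, and 12 rose and 2 fell with the block, and Irf1 rose by 0.94 (SE 0.19, adjusted p = 0.016). Without tumor 2 the list did not pass (adjusted p = 0.167). The quiescence list did not pass (adjusted p = 0.338), but Foxo3, a transcription factor held in check by growth factor signaling, rose by 0.90 (SE 0.14, adjusted p = 0.00623). Mitosis genes fell as a list (median -0.59, adjusted p = 0.00344; adjusted p = 0.74 with an estimated correlation), yet 0 of 35 members passed in limma, over all genes, over the list alone or with the block. The tumors differed: the mean change was -1.53, -1.16, 0.55, 1.48 and -2.33 in tumors 1 to 5, so the list was higher in 2 of them. Leaving out tumor 1 or tumor 5 ended the call (adjusted p = 0.146 and 0.387), and Mki67 changed by -0.98 (SE 0.75, adjusted p = 0.534).

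The largest single changes included genes outside these lists. The apolipoprotein Apoc2 fell by 5.01 (SE 0.71, adjusted p = 0.00362), 32.3-fold. Sprr2h, a small proline-rich protein of keratinizing epithelia (-4.88), the leukocyte tetraspanin Cd53 (-4.49), the zinc transporter Tmem163 (-4.05), the intestinal cadherin Cdh17 (-3.80), the macrophage mannose receptor Mrc1 (-3.67), aggrecan, Acan (-3.44), and the kinase Prkg2 (-3.38) fell as well. Among those that rose were the serine protease Prss23 (3.25), the cytochrome P450 Cyp1b1 (at least 3.17, as it lay under the filter level of 5.83 in spheres), the endonuclease-like protein Endod1 (2.86), the RNA-binding protein Bicc1 (2.41) and the cytokine Il18 (2.03). The ductal genes Krt23 (-3.20) and Slc4a4 (1.64) moved in opposite directions. Adjusted p ran from 0.000865 for Tmem163 to 0.0152 for Cdh17, and each of these genes changed one way in 5 of 5 pairs and kept its call with any 1 array left out. Others with large changes did not: Plet1 (3.43, adjusted p = 0.03), the largest rise, lost its call without 8 of the 10 arrays taken singly, all but the sphere array of tumor 1 and the surviving-cell array of tumor 3 (up to 0.0751). The collagenase Mmp13 (-4.01, adjusted p = 0.0428) lost it without 7, all but the sphere array of tumor 1 and the surviving-cell arrays of tumors 2 and 3 (up to 0.1), or with no filter, and the chromatin remodeler Smarcd3 (2.91, adjusted p = 0.0186) without the sphere array of tumor 2 (0.0518). With only the 10 arrays compared in the fit none of these 3 passed. Cd44 and Prom1, used as markers of tumor-initiating cells, were higher by 0.71 and 1.81 in 5 of 5 pairs and passed only with the block (adjusted p = 0.354 and 0.123 without it, 0.00431 and 0.00333 with it).

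Across all genes 342 rose and 226 fell, 568 in all, 101 and 113 of them at least 2-fold; 555 of the 568 moved one way in all 5 pairs. Over all tested genes that share was 28.7%, and chance gives 6.25%. With the tumor as a block 3864 passed (2352 higher, 1512 lower), among them all 568. The remaining lists did not pass: mitochondrial ribosome (adjusted p = 0.0986; 0.0463 and lower with the block), adipocyte markers (0.0547), cytokines and NF-kB targets (0.116; 0.0442 without tumor 2), pentose phosphate, hexosamine and nucleotide synthesis (0.333), mitochondrial biogenesis regulators (0.338), DNA replication (0.53; 0.00154 and lower without tumor 4), NRF2 targets and hypoxia (0.51 each), mesenchymal genes (0.404), stem cell markers (0.83), p53 targets, epithelial genes and ductal markers (0.989 each), acinar (0.688) and endocrine markers (0.338). Markers of fibroblasts (0.663), macrophages (0.369), lymphocytes (0.369), neutrophils and mast cells (0.606), endothelium (0.459), pericytes (0.834) and nerve (0.503) did not pass, and red blood cell markers had 3 members, too few to test. Of the 37 lists 11 moved one way in 5 of 5 tumors, 6 of the 9 called and 5 of the others. The count of 568 fell to 261 and 280 without the sphere or the surviving-cell array of tumor 2, to 364 and 346 for tumor 3, and to 334 and 366 for tumor 4. Without all arrays of tumor 2, 3 or 4 it was 66, 107 or 233, and without tumor 3 the balance turned to 50 higher and 57 lower. With only the 10 arrays compared in the fit the count was 260.

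**Figure D2:**
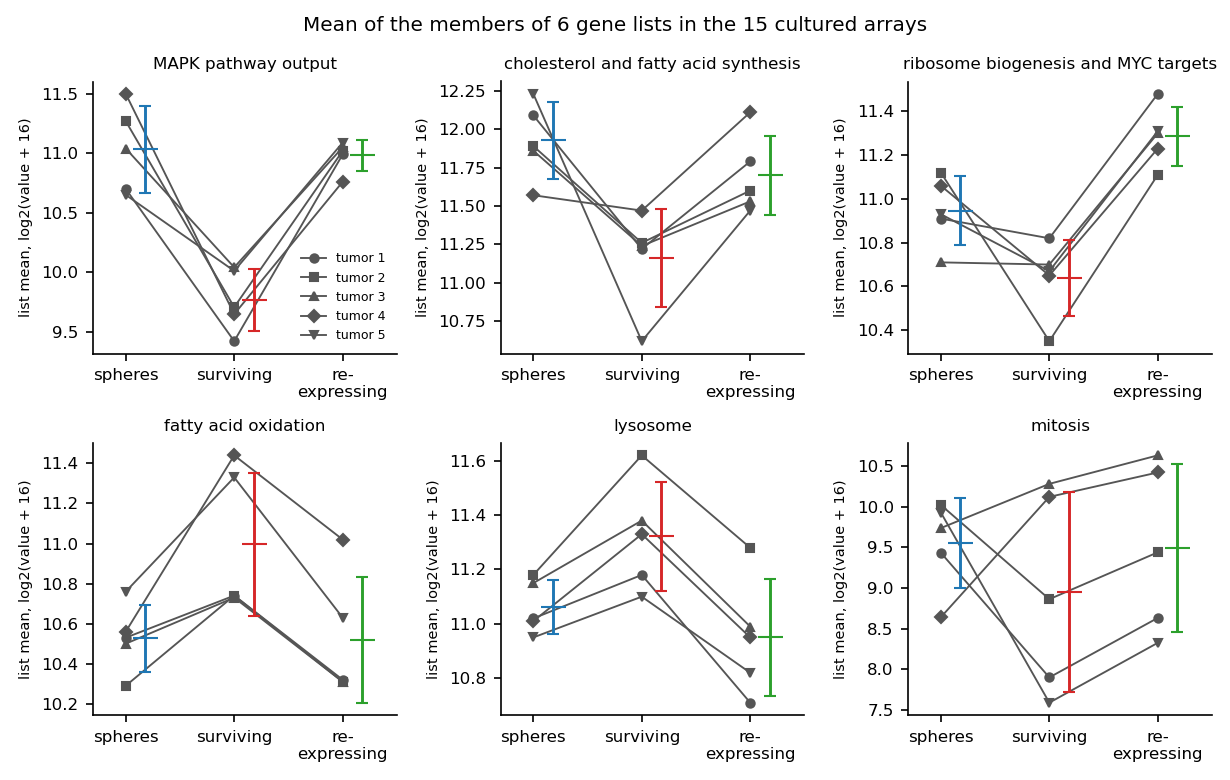
Mean log2(value + 16) over the members of 6 gene lists in spheres, surviving cells and re-expressing cells, 1 line per tumor (marker shape), with colored bars giving the mean and SD of the 5 arrays. The MAPK list fell in each tumor on ablation (by 0.64 to 1.85) and was higher again in each after re-expression, while the mitosis list moved both ways on ablation.

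Re-expressing cells were then compared with the surviving cells, to see what differed after 24 hours of Kras. MAPK output rose in each tumor within the day, by 1.01 to 1.57 as a list mean. Dusp6 rose by 1.75 (SE 0.20, limma adjusted p = 0.00366), Etv4 by 1.62 (SE 0.26, adjusted p = 0.0114), Dusp5 by 2.65 (SE 0.42, adjusted p = 0.0114) and the AP-1 subunit Fosl1 by 3.03 (SE 0.49, adjusted p = 0.0114), all in 5 of 5 pairs. Of 25 list members 10 rose, 15 adjusted over the list alone and 17 with the block (median 1.27, camera adjusted p = 1.75e-17; adjusted p = 0.0148 with an estimated correlation, lost at 0.343 when the block is added to it). Spry4 rose by 1.98 (SE 0.37, adjusted p = 0.0218); its call was lost without the arrays of surviving cells 2 or 3 or of re-expressing cells 1 or 4 (up to 0.0637). Ccnd1 was 0.84 higher in 5 of 5 pairs and passed only with the block (adjusted p = 0.0894, 0.00342 with it).

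Ribosome biogenesis and MYC targets had the smallest p of any list. Of its 40 members 15 rose, 37 adjusted over the list alone and 39 with the block, and the list mean rose by 0.58 to 0.76 in each of the 5 tumors (median 0.64, adjusted p = 1.83e-32; adjusted p = 0.0219 with an estimated correlation, lost at 0.387 when the block is added to it). The spermidine synthase Srm rose by 1.26 (SE 0.20, adjusted p = 0.0114), the nucleolar protein Nop56 by 1.03 (SE 0.16, adjusted p = 0.0114) and Cad, which starts pyrimidine synthesis, by 0.88 (SE 0.14, adjusted p = 0.0114). Myc mRNA itself changed by 0.06 (adjusted p = 0.899). DNA replication genes rose in 5 of 5 tumors (median 0.77, adjusted p = 2.67e-13; adjusted p = 0.39 with an estimated correlation), with 0 of 33 members passing in limma over all genes, 11 over the list alone and 12 with the block. Mitosis genes rose in 5 of 5 tumors by 0.296 to 0.735 as a list (median 0.51, adjusted p = 0.00201; adjusted p = 0.803 with an estimated correlation), with 0 of 35 members passing in any of these fits and Mki67 at 0.86 (adjusted p = 0.68). Cholesterol and fatty acid synthesis rose in 5 of 5 tumors (3 of 22 members, 6 over the list alone, 9 with the block; median 0.52, adjusted p = 3.3e-09, and adjusted p = 0.233 with an estimated correlation). Pentose phosphate, hexosamine and nucleotide synthesis rose (2 of 25, 3 over the list alone, 7 with the block; median 0.17, adjusted p = 0.000405, and adjusted p = 0.116 with an estimated correlation). So did glycolysis (1 of 18, 3 over the list alone, 5 with the block; median 0.22, adjusted p = 0.00592, and adjusted p = 0.233 with an estimated correlation). The mitochondrial ribosome rose by a small amount (0 of 70 in limma over all genes and over the list alone, 10 with the block; median 0.09, adjusted p = 0.00592, and adjusted p = 0.475 with an estimated correlation). These 3 lists were higher in 5 of 5 tumors. Slc2a1 (1.15) and Hk2 (0.55) were higher in 5 of 5 pairs and passed only with the block (adjusted p = 0.0119 and 0.0404, against 0.155 and 0.365 without it). Ldha rose by 0.65 (SE 0.13, adjusted p = 0.0345), a call lost without 9 of the 10 arrays taken singly (up to 0.0929).

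There were 5 lists that fell on re-expression, each lower in 5 of 5 tumors. Over all 37 lists tested the mean moved one way in 5 of 5 tumors for 26, 13 of them not called. Fatty acid oxidation fell (1 of 22 members, 8 over the list alone, 15 with the block; median -0.52, adjusted p = 3.47e-08, and adjusted p = 0.12 with an estimated correlation). Lysosomal genes fell (0 of 39 in limma over all genes and over the list alone, 22 with the block; median -0.37, adjusted p = 9.35e-09, and adjusted p = 0.0818 with an estimated correlation). Autophagy genes fell (2 of 32, 7 over the list alone, 14 with the block; median -0.30, adjusted p = 1.21e-06, and adjusted p = 0.0635 with an estimated correlation). Genes of quiescence fell (2 of 27, 3 over the list alone, 8 lower and 1 higher with the block; median -0.35, adjusted p = 0.000704, and adjusted p = 0.0512 with an estimated correlation), and Foxo3 dropped by 0.91 (SE 0.14, adjusted p = 0.0114). Interferon-response genes fell (0 of 31 in limma over all genes and over the list alone, 7 with the block; median -0.33, adjusted p = 0.000405, and adjusted p = 0.462 with an estimated correlation). Complex I was 0.10 lower at the median without passing (adjusted p = 0.105; 0.0493 with no filter). Ppargc1a was 1.59 lower in 5 of 5 pairs and passed only with the block (adjusted p = 0.338, 0.0148 with it).

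Among other large changes, the membrane-associated protein Lratd1 rose by 3.15, Tmem163 by 3.07 and the glycoprotein hormone Stc1 by 2.74, and Klhl24 fell by 1.33, Crebrf by 1.29 and the MYC antagonist Mxd4 by 1.09 (adjusted p from 0.00642 for Crebrf to 0.0114). Sprr2h rose by 5.06 (SE 0.92, adjusted p = 0.0203) and Mrc1 by 3.29 (SE 0.60, adjusted p = 0.0203). The Sprr2h call was lost without the array of surviving cells 2 or of re-expressing cells 3 or 5 (up to 0.0624), and the Mrc1 call without surviving cells 2 or 4 or re-expressing cells 1 or 3 (up to 0.0677). In all 95 genes rose and 74 fell, 169 in total, 36 and 16 of them at least 2-fold, and all 169 moved one way in 5 of 5 pairs, as did 47.8% of all tested genes. With the tumor as a block 2666 passed, with the balance turned: 1063 rose and 1603 fell. The count of 169 fell to 103, 41, 99, 95 and 97 without the array of surviving cells 1 to 5 in turn (41 is for number 2), to 41, 79 and 73 without re-expressing cells 1, 3 or 5, and to 37, 16, 1, 75 and 3 without all arrays of tumors 1 to 5. The other 23 lists, besides complex I, did not pass. Complexes II to IV (adjusted p = 0.248), ATP synthase (0.342), mitochondrial biogenesis regulators (0.102), the TCA cycle (0.442), NRF2 targets (0.102), hypoxia (0.187), the unfolded protein response (0.232), p53 targets (0.289) and cytokines (0.591) were among them. So were epithelial (0.424), mesenchymal (0.59), stem cell (0.792), acinar (0.581), endocrine (0.266), ductal (0.59), fibroblast (0.776), macrophage (0.59), lymphocyte (0.0667), neutrophil and mast cell (0.0775), endothelial (0.59), pericyte (0.718), adipocyte (0.59) and nerve (0.776) genes.

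Genes that fell on ablation tended to rise on re-expression, and the reverse. Of the genes called in both comparisons 54 fell and then rose, Dusp6, Etv4, Dusp5 and Tmem163 among them, and 42 rose and then fell, such as Foxo3. These counts can be no larger than the number of re-expression calls, which was 41 without the array of surviving cells 2 or of re-expressing cells 1, and 1 and 3 without tumors 3 and 5. For independent sets of these sizes 1.48 and 1.75 would be expected. A single gene, B330016D10Rik, fell in both (by 0.35 and 0.42); it is named after its values were seen. Across genes, which are not independent replicates, the changes correlated at -0.768. Both comparisons use the same surviving-cell arrays, and simulated groups with no effect gave -0.5 (-0.533 to -0.466). The covariance was -0.138 against a simulated -0.0447, a difference of -0.0933. These simulated arrays carried no tumor effect, so the pairing of the real arrays was left out of them. With the surviving-cell arrays split, 2 or 3 to each comparison, the correlation was -0.378 at the median of 20 assignments, the covariance -0.0888, and the median count of opposite calls was 0 (0 to 1), at which size few genes passed in either comparison (medians of 28 and 0). Each split set the surviving cells of 2 or 3 tumors against all 5 arrays of the other group. Differences between tumors then enter both comparisons with the same sign and pull the correlation upward. The value of -0.378 is therefore not simply the correlation freed of the shared arrays. With the tumor as a block 588 fell and then rose and 1083 did the reverse. Groups with no effect simulated for that fit, with the shared arrays, gave a correlation of -0.498 and a covariance of -0.012.

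**Figure D3:**
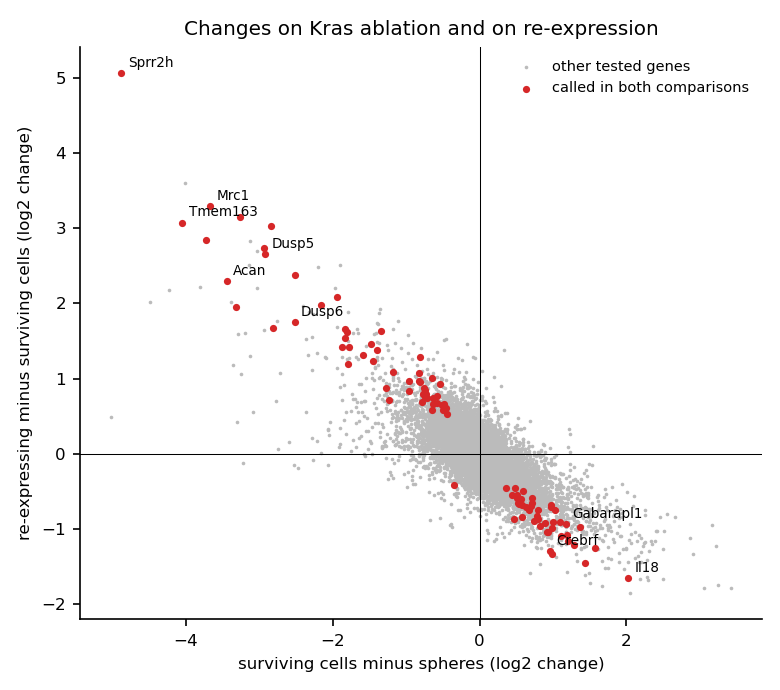
Log2 change of each tested gene on Kras ablation (surviving cells minus spheres, across) against its change on re-expression (re-expressing minus surviving cells, up); each point is 1 of 14503 genes. Red points passed in both comparisons; 54 lie at the upper left, 42 at the lower right and 1 at the lower left, and part of the tilt comes from the surviving-cell arrays that both axes share.

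The re-expressing cells were also set against the spheres, to see what still differed after 24 hours of Kras. Re-expressing cells descend from cells that outlived 8 days of ablation, and spheres do not. Selection of survivors, culture history and an incomplete return therefore cannot be told apart here. Few single genes passed in the fit that leaves the pairing out, against 1007 with the tumor as a block. Tubb5 (0.66), the noncoding RNA Dancr (0.75) and Zfp512b (0.82) were higher and Apoc2 (-4.52), B330016D10Rik (-0.77) and Rab29 (-0.59) were lower, the 6 genes that passed (limma adjusted p from 0.00949 for B330016D10Rik to 0.0496), each in 5 of 5 pairs, as for 16.1% of all tested genes. Apoc2 stayed at 9.11 ± 1.55 in re-expressing cells, against 13.63 ± 0.89 in spheres. MAPK output did not differ as a list (median -0.06, adjusted p = 0.637), though Dusp6 was 0.77 lower in 5 of 5 pairs and passed with the block (adjusted p = 0.233, 0.0393 with it). Each of the 6 genes lost its call when some 1 array was left out (highest adjusted p 0.0561 for B330016D10Rik and 0.188 for Zfp512b) and with only the 10 arrays in the fit (0.0696 for B330016D10Rik to 0.351 for Rab29). The count of 6 became 0 or 1 without spheres 2 or 3 or re-expressing cells 1 to 4, 2 without re-expressing cells 5, and 1007 (514 higher, 493 lower) with the tumor as a block.

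Of the lists, 10 differed from the spheres, 4 higher and 6 lower, with 0 members passing in limma over all genes in any list (1157 of all genes had an unadjusted p under 0.05). Ribosome biogenesis and MYC targets were higher (39 of 40 members above 0, 9 passing over the list alone and 10 with the block, 4 of 5 tumors; median 0.30, adjusted p = 2.09e-15, and adjusted p = 0.392 with an estimated correlation). DNA replication was higher, with 33 of 33 members above 0 in the fit, 0 passing over the list alone and 2 with the block, and a higher list mean in 4 of 5 tumors (median 0.71, adjusted p = 2.48e-15, and adjusted p = 0.417 with an estimated correlation), and Pcna at 0.63 (adjusted p = 0.392). The unfolded protein response and ATF4 list was lower in 4 of 5 tumors (median -0.45, adjusted p = 0.000278, and adjusted p = 0.417 with an estimated correlation). Each of the other 7 calls was lost without at least 1 tumor. Cholesterol and fatty acid synthesis was lower (-0.26, adjusted p = 0.00235; 0.276 without tumor 5), as were autophagy (-0.143, 0.00239; 0.0675 without tumor 1), lysosome (-0.09, 0.0278; 0.328, 0.0619 and 0.0744 without tumors 1, 3 and 5), quiescence (-0.205, 0.0235; 0.309 and 0.0744 without tumors 1 and 5) and adipocyte markers (-0.32, 0.0228; 0.0796 without tumor 4, 0.0738 with no filter and 0.0669 with a filter at the 50th percentile). Pentose phosphate, hexosamine and nucleotide synthesis (0.25, 0.0145; 0.0515 and 0.0969 without tumors 3 and 4) and mesenchymal genes (0.15, 0.0439; 0.277, 0.0515 and 0.0744 without tumors 2, 3 and 5, 0.0631 with the stricter filter and 0.105 with the mean of all probe sets) were higher. These 7 had at most 1 member passing over the list alone, up to 5 with the block, and an adjusted p of 0.392 to 0.729 with an estimated correlation, and the adipocyte list was lower in 5 of 5 tumors, the other 6 moving their way in 4 of 5. The other 27 lists tested did not pass. Cytokines and NF-kB targets came nearest (0.0828; 0.02 and higher with the block). MAPK output, complex I, complexes II to IV, ATP synthase, the mitochondrial ribosome, mitochondrial biogenesis regulators, the TCA cycle, glycolysis, fatty acid oxidation, mitosis, NRF2 targets, hypoxia, p53 targets and the interferon response ran from 0.254 to 0.875. Epithelial, stem cell, acinar, endocrine, ductal, fibroblast, macrophage, lymphocyte, neutrophil and mast cell, endothelial, pericyte and nerve genes ran from 0.267 to 0.941.

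Spheres were last compared with the bulk tumors they were grown from. Bulk tumor is a mixture of cell types, so loss of other cells and changes within tumor cells cannot be told apart. This holds for every list and gene of the comparison, higher or lower. Stromal markers were far lower in the spheres. Of 26 fibroblast markers 25 fell, all 26 adjusted over the list alone (median -5.19, camera adjusted p = 3.07e-30; adjusted p = 0.0332 with an estimated correlation, lost at 0.166 when the block is added to it). Collagen III, Col3a1, fell by at least 9.38 (SE 0.19, limma adjusted p = 2.85e-10), from 14.81 ± 0.43 to 5.43 ± 0.11. For Col3a1, Ctss, Pecam1 and Rgs5 the sphere mean lay under the filter level of 5.83, so the size of the fall is a lower bound. Macrophage and monocyte markers fell for 24 of 27 members, 24 over the list alone (median -3.13, adjusted p = 2.59e-19; adjusted p = 0.0912 with an estimated correlation), with lysozyme Lyz2 down by 7.26 (SE 0.31, adjusted p = 7.39e-08) and the protease Ctss by at least 8.28. Endothelial markers fell for 19 of 23, also 19 over the list alone (median -2.55, adjusted p = 5.61e-18; adjusted p = 0.00266 with an estimated correlation), Pecam1 by at least 2.96 (SE 0.14, adjusted p = 1.8e-07). Pericyte and smooth muscle markers fell for 12 of 15, 12 over the list alone (median -2.22, adjusted p = 1.07e-11; adjusted p = 0.00266 with an estimated correlation), Rgs5 by at least 6.86 and Acta2 by 5.85. Mesenchymal genes, 22 of 31 lower and 23 over the list alone, went with them (median -3.08, adjusted p = 2.59e-19; adjusted p = 0.0148 with an estimated correlation). Neutrophil and mast cell markers fell for 4 of 14, 4 over the list alone (median -0.805, adjusted p = 0.00317; adjusted p = 0.067 with an estimated correlation). All 6 lists were lower in 5 of 5 tumors. Lymphocyte (adjusted p = 0.185), adipocyte (0.853) and nerve (0.195) markers did not pass.

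**Figure D4:**
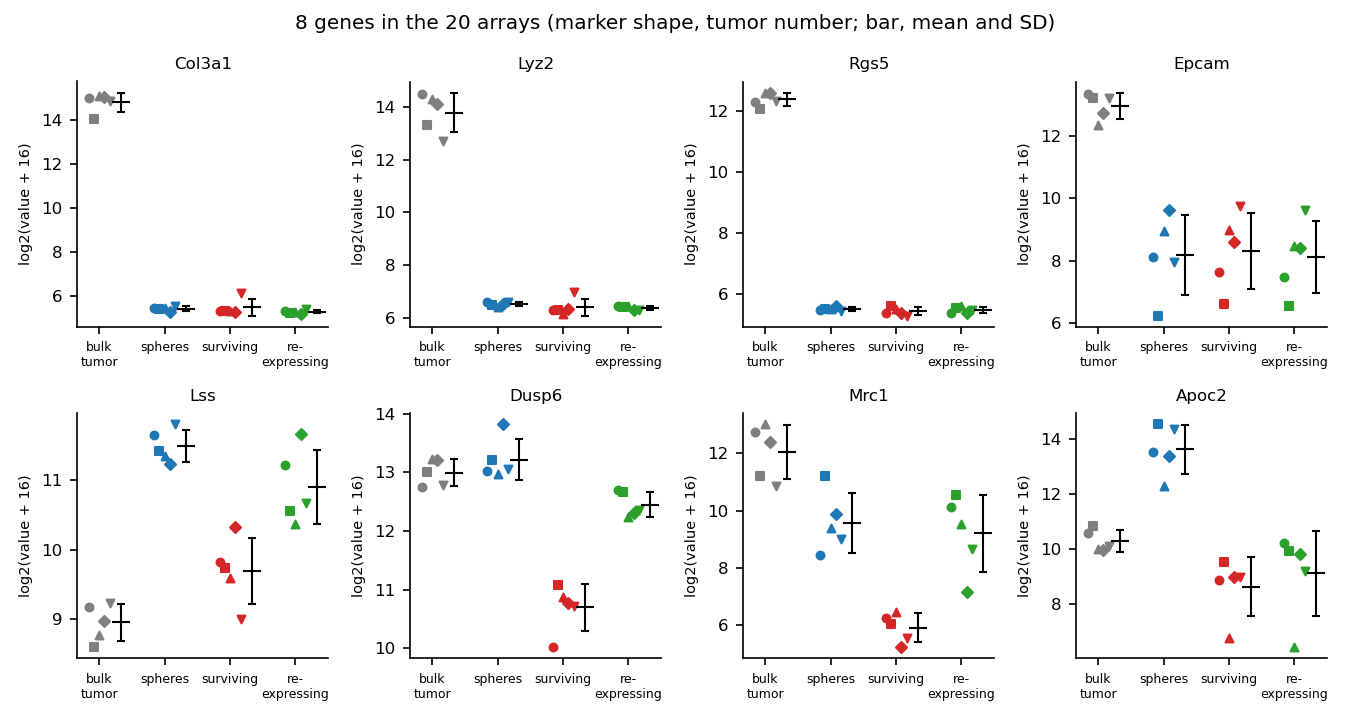
Log2(value + 16) of 8 genes in the 20 arrays, with marker shape for the tumor and bars for the mean and SD of each group of 5. Col3a1, Lyz2 and Rgs5 were high in bulk tumor only, Lss was highest in spheres, Dusp6 and Mrc1 dipped in surviving cells, and Apoc2 stayed low after re-expression (9.11 ± 1.55 against 13.63 ± 0.89 in spheres).

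The lists that were higher in the spheres cover cholesterol and fatty acid synthesis, the mitochondrial ribosome and respiratory chain, ribosome biogenesis, and the NRF2 and ATF4 responses. Of 22 cholesterol and fatty acid synthesis genes 20 rose, 20 over the list alone (median 1.69, adjusted p = 1.84e-09; adjusted p = 0.13 with an estimated correlation), with Lss up by 2.53 (SE 0.16, adjusted p = 1.59e-06) and the desaturase Scd1 by 2.76 (SE 0.25, adjusted p = 2.4e-05). The mitochondrial ribosome rose for 53 of 70 members, 57 over the list alone (median 0.75, adjusted p = 1.21e-12; adjusted p = 0.069 with an estimated correlation), Mrpl16 by 1.49. Complex I rose for 18 of 33, 21 over the list alone (median 0.46, adjusted p = 0.00017; adjusted p = 0.273 with an estimated correlation), complexes II to IV for 12 of 23, 13 over the list alone (median 0.33, adjusted p = 0.00374), ATP synthase for 6 of 16, 6 over the list alone and 4 with the block (0.34, 0.0269), the TCA cycle for 10 of 20, 11 over the list alone (0.45, 0.00552), and mitochondrial biogenesis regulators for 10 of 29, 12 over the list alone (0.37, 0.00418). For these last 4 lists the adjusted p was 0.287 to 0.356 with an estimated correlation. Ribosome biogenesis and MYC targets rose for 22 of 40, 26 over the list alone (median 0.565, adjusted p = 3.02e-06; adjusted p = 0.287 with an estimated correlation), and Myc itself by 0.69 (SE 0.18, adjusted p = 0.0139). Pentose phosphate, hexosamine and nucleotide synthesis rose for 9 of 25, 9 over the list alone (0.33, 0.0348; adjusted p = 0.273 with an estimated correlation). Among NRF2 and antioxidant genes 13 of 24 rose, 14 over the list alone. Their median was 0.76 (camera adjusted p = 0.000535, and adjusted p = 0.287 with an estimated correlation). The unfolded protein response and ATF4 list had 14 of 30 members higher and 2 lower, 17 and 3 over the list alone. Its median was 0.82 (camera adjusted p = 0.00453, and adjusted p = 0.287 with an estimated correlation). In that list the cystine transporter Slc7a11 rose by 4.47 (SE 0.55, limma adjusted p = 0.000227). The serine synthesis enzymes Psph and Psat1 rose by 3.40 and 2.49 and the glutathione-degrading enzyme Chac1 by 3.47. The largest rise named here was that of Cth, which makes cysteine, at 5.13 (SE 0.44, adjusted p = 1.66e-05). These 11 lists were higher in 5 of 5 tumors; over all 37 lists 28 moved one way in 5 of 5.

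Several epithelial and differentiation lists were lower in the spheres than in the tissue, whose mix of cells also differs. Epithelial genes fell for 10 of 32 members, 10 over the list alone (median -0.55, adjusted p = 7.79e-05; adjusted p = 0.383 with an estimated correlation), with the adhesion molecule Epcam down by 4.77 (SE 0.53, adjusted p = 0.000113) and the tight junction protein Cldn4 by 4.82, while E-cadherin, Cdh1, changed by -0.32 (adjusted p = 0.461). Acinar markers fell (6 of 20 lower and 2 higher, 7 and 3 over the list alone, with 6 and 1 with the block; median -1.26, adjusted p = 0.00317, and adjusted p = 0.45 with an estimated correlation), Reg1 by 5.67 (SE 0.54, adjusted p = 3.98e-05). Ductal markers fell (6 of 20 lower and 1 higher, the same over the list alone, 5 and 2 with the block; median -0.81, adjusted p = 0.011, and adjusted p = 0.416 with an estimated correlation), a call lost without tumor 2 (adjusted p = 0.0711). The endocrine list fell (2 of 10 lower, 0 in limma over the list alone; median -0.37, adjusted p = 0.0412, and adjusted p = 0.416 with an estimated correlation) but not with the block (0.0766), after quantile normalization (0.0669), with the mean of all probe sets (0.0906) or without tumor 1, 4 or 5 (0.101, 0.0947 and 0.0555). Hypoxia genes were lower, 11 of 25 with 1 higher, the same numbers over the list alone (median -0.67, adjusted p = 0.000214, and adjusted p = 0.381 with an estimated correlation), Car9 by 4.07 (SE 0.69, adjusted p = 0.00154). Interferon-response genes were lower, 8 of 31, 8 over the list alone (median -0.29, adjusted p = 0.0031, and adjusted p = 0.416 with an estimated correlation). Stem and tumor-initiating cell markers were lower on balance, 11 lower and 4 higher of 32, 14 and 4 over the list alone (median -0.28, adjusted p = 0.00766, and adjusted p = 0.273 with an estimated correlation), with Dclk1 down by at least 3.07, Cxcr4 by at least 3.03 (both under the filter level in spheres) and Cd44 by 1.49 and Aldh3a1 up by 2.65. Quiescence genes were lower, 7 with 2 higher of 27, 8 and 2 over the list alone, 7 and 1 with the block (median -0.18, adjusted p = 0.0172, and adjusted p = 0.13 with an estimated correlation). MAPK output was slightly lower (median -0.28, adjusted p = 0.0315, and adjusted p = 0.416 with an estimated correlation) with 3 of 25 lower and 1 higher, 1 and 1 over the list alone; the call was lost without tumor 5 (adjusted p = 0.31) and with the mean of all probe sets (0.059), and Dusp6 differed by 0.22 (adjusted p = 0.381).

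Between spheres and bulk tumor 2662 genes rose and 1890 fell, 4552 in all, 856 and 1205 of them at least 2-fold. The median change over all tested genes was 0.118, so changes of that size sit at the middle of the distribution. The balance depends on the scaling: with each array centred on its median 3529 rose and 1710 fell, 67.4% higher against 58.5%. With the tumor as a block 4625 passed, 4112 of them also without it. Without all arrays of tumor 3 the count was 2957. Glycolysis (adjusted p = 0.0836), fatty acid oxidation (0.0881), autophagy (0.333), lysosome (0.455), DNA replication (0.904), p53 targets (0.333) and cytokines (0.333) did not pass as lists. Nor did mitosis, which passed and was higher with the block (adjusted p = 0.125, 0.0415 with it; Mki67 -0.27, adjusted p = 0.541). The RNA of 1 bulk tumor, number 2, had the highest ratio of 3' to 5' Gapdh probe sets (1.05, against 0.277 ± 0.462 over the 5 bulk tumors and -0.147 in spheres, log2), and 3972 genes passed without that array.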

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

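The tests of the mitosis pattern below were chosen only after the result was seen. Of 29 groups of 5 values tested for a value far from the others, 12 of them on array quality, 2 had one, where chance gives 1.4; 0 of the 2 were on array quality. Col3a1 was 14.05 in bulk tumor 2 against 14.86 to 15.09 in the other bulk tumors, and Dusp6 was 13.82 in the spheres of tumor 4 against 12.97 to 13.21 in the others.

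Probe sets that carry no gene symbol or several also hold signal. Of the 5158 bright enough to test, 137 passed for surviving cells against spheres, 21 for re-expressing against surviving cells, 1 for re-expressing cells against spheres and 965 for spheres against bulk tumor, that is 2.66%, 0.407%, 0.0194% and 18.7%. Among probe sets with 1 named gene the shares were 3.77%, 0.712%, 0.0151% and 28.9%.

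Mitosis genes changed in opposite directions in different tumors on ablation: of its 35 members 34, 35, 2, 1 and 35 were lower in tumors 1 to 5. An exchange of arrays between tumors could give this. It is excluded as far as the test goes, since with mitosis and DNA replication genes left out the surviving cells deviated most like the spheres of their own tumor in 5 of 5. Cultures in which Kras stayed on could give it too, but the MAPK list changed by -0.641 or more strongly downward in every tumor (the weakest was tumor 5, SE over its members 0.202, where mitosis fell most). Cultures that resumed division without Kras might remain as a biological reading; cell counts were not measured.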

How the results depend on the processing

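The block with an estimated correlation was chosen only after the result was seen; the other alternatives were set beforehand. No named gene that passed in the main fit or in an alternative turned its direction between them. Nor did any such list among the 17, 14, 11 and 22 followed through the alternatives in the 4 comparisons. Turns of results that passed in neither were not counted. The balance of calls did turn: re-expression went from 95 higher and 74 lower to 1063 and 1603 with the tumor as a block. Ablation went from 342 and 226 to 50 and 57 without tumor 3. For surviving cells against spheres, 568 genes became 3864 with the tumor as a block and 260 with only the 10 arrays, and ran from 66 (without tumor 2) to 786 with arrays or tumors left out. The 9 lists became 1 with an estimated correlation and 0 with the block and an estimated correlation (MAPK output 0.597), and 8 to 11 with a tumor left out. For re-expressing against surviving cells, 169 genes became 2666 with the block and 1 (without tumor 3) to 127 with an array or tumor left out; the 13 lists became 2 with an estimated correlation, 0 with the block and that correlation, and 13 to 14 with a tumor left out. The share of higher calls moved from 56.2% to 39.9% with the block. For re-expressing cells against spheres, 6 genes became 1007 with the block, 0 with the 50th percentile filter or only the 10 arrays, 1 with trend and robust, 2 with quantile, median centring or pseudocount 1, 3 with the mean of probe sets, and 0 to 9 with arrays or tumors left out; the 10 lists became 0 with an estimated correlation, with or without the block, and 6 to 10 with a tumor left out. For spheres against bulk tumor, 4552 genes stayed between 2957 and 4573 with arrays or tumors left out and were 4625 with the block; the 26 lists became 4 with an estimated correlation, 3 with the block and that correlation (fibroblast markers 0.166), and 23 to 26 with a tumor left out. The 96 opposite calls became 1671 with the block, 0 with the surviving-cell arrays split, and 99 with no filter. In the fit of the cultures the median SE of a log2 change was 0.105 with the block and 0.177 without it. Leaving the pairing out therefore accounts for part of the lower counts in the cultures. The cause of the other changes was not tested. Of the named genes, 1390 of 1690 alternatives left the call the same on ablation, 952 of 1299 on re-expression, 538 of 649 for re-expressing cells against spheres and 1894 of 1947 for spheres against bulk tumor, with 292, 343, 108 and 45 weaker. For lists it was 193 of 221, 157 of 182, 106 of 143 and 242 of 284. Among the calls named in the text, the block changed no others than those printed beside them. Signal over background limits the dim genes: 79.7% of genes passed the filter.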

Other observations

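Of the tests that follow, the first 2 on complex I were set beforehand and the others were chosen only after the result was seen. Mrc1 and Cd53 mark macrophages in tissue, and their fall on ablation might come from macrophages carried into the spheres. If so, the abundant macrophage genes Cd14, Lyz1, Lyz2, C1qa, C1qb, Fcgr3 and Ctss should persist in spheres to the same degree. A floor of the values was first taken off both groups. The median share of bulk intensity that these genes kept was 0.287, 0.424, 0.185, 0.261 and 0.768% in tumors 1 to 5. These are upper bounds, since Lyz1, C1qa, C1qb and Ctss lay under the filter level of 5.83 in spheres. Mrc1 kept 4.65, 100, 7.7, 17 and 26.1% in tumors 1 to 5 and Cd53 7.55, 211, 32.6, 86.9 and 19.6%, so macrophages at that level do not account for either gene; Cd14 was the exception, at up to 90.2%. Expression of Mrc1 and Cd53 by the tumor cells may be 1 reading that remains. The test covers macrophages only, and other cell types carried into the spheres were not tested.

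The small rise of complex I genes on ablation could be a shift that depends on intensity, but its median of 0.172 lay at percentile 99.6 of 10000 random lists matched on expression. After quantile normalization 93.9% of the change was left, so remaining differences in distribution between the deposited arrays account for little of it. Those arrays were already close, with a mean array median of 87.26 in spheres and 87.92 in surviving cells. An effect of the authors' own normalization cannot be tested this way. A single tumor does account for much of it: without tumor 4, 47.7% of the median was left (0.0821), against 0.178 to 0.204 without any other. The complex I rise may therefore be mostly that of 1 tumor. Fatty acid oxidation lay at percentile 100 of its matched lists, which does not test dependence on 1 tumor. Matched lists draw genes singly, so correlation among the members of a list is not in these percentiles. For fatty acid oxidation the camera adjusted p was highest without tumor 4 among the tumors left out (0.000582). With an estimated correlation it was 0.582.

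Regrouping the arrays gives what chance could reach. For genes, 1 of 100 splits, the real grouping itself, gave as many calls in each comparison; the highest of the others was 0 for ablation, 2 for re-expression, 1 for re-expressing cells against spheres and 22 for spheres against bulk tumor. With the block there are only 16 splits, too few for a share under 0.05; again 1 split, the real one, was as large (highest other 1, 0, 50 and 0). For the number of lists called, 43, 33 and 31 of 100 splits were as large in the 3 comparisons of cultures, with up to 16 lists called, so chance could explain those totals, and 4 of 100 for spheres against bulk tumor. The preset correlation of 0.01 is lower than that of many lists, so the number of lists called is no evidence by itself. Nor is one direction in 5 of 5 tumors: 11 of 37 lists on ablation and 26 of 37 on re-expression had it.

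An exact permutation of the 10 arrays gives each list mean a two-sided p of at least 0.00794 (252 regroupings). On ablation that smallest p was reached by MAPK output and by cholesterol and fatty acid synthesis (adjusted p = 0.147 over 37 lists). The p was 0.0159 for the unfolded protein response and 0.341 for mitosis. On re-expression it was reached by ribosome biogenesis, MAPK output, cholesterol synthesis and autophagy (adjusted p = 0.0734). These regroupings ignore the pairing, so spread between tumors enters them. Sign changes within the 5 pairs keep it, but with 32 of them no exact two-sided p can be under 0.0625. Every list that moved one way in 5 of 5 tumors reaches that value, 11 of 37 on ablation and 26 of 37 on re-expression. MAPK output was among them in both comparisons (adjusted p = 0.21 and 0.0889), so this does not set it apart. Mitosis on ablation had an exact p of 0.438.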
